A study of Mus musculus with 8 samples.

How the data were processed

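Messenger RNA of mouse bone-marrow-derived macrophages was sequenced in 8 libraries, 2 for each combination of genotype (WT or KAT8-deficient) and treatment (untreated, or R848 at 100 ng/ml for 6 h). Per the labels' protocols, total RNA was purified with DNase treatment, messenger RNA was captured on beads, and libraries were made with a Vazyme kit. The deposited values are counts per Ensembl gene, 1 column per library, per the file headers. Per the submitters' processing notes, the tools were StringTie 1.3.0, HISAT2 and edgeR on the mm10 genome, and the notes do not say what each was used for. Read trimming, the gene annotation, the counting settings, the strand setting and the read length are not given in the sources used here. Poly(A) capture favours polyadenylated transcripts, so most histone messenger RNA is poorly covered. Reads shared by near-identical or overlapping genes could have been split in the counting, and some genes open to this are named as uncertain.

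All values were whole numbers, and each of the 8 columns was matched to its sample by name, with 0 columns left over. Total counts ran from 18550977 to 21384532 per library, and at this depth the floor of 3 counts corresponds to 0.14 to 0.162 CPM. Such floors cover counting error only. Symbols and coordinates came from GENCODE M21 for GRCm38, the same build as mm10. Of 34745 gene identifiers, 34267 had a symbol and 34344 a position, and the 478 without a symbol held 0.138% of all counts. The replicates of each group differed by more than counting error, with chi-square per degree of freedom from 7.83 to 12.71, so they are separate libraries. The labels do not say whether they came from separate animals or cultures.

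Genes with low counts were removed with edgeR's filterByExpr, which left 14040 genes. Counts were normalised by TMM, and all 8 libraries were fitted together with edgeR's quasi-likelihood model, 1 mean per group, 4 residual degrees of freedom and a common biological coefficient of variation of 0.096. Contrasts gave the R848 response in each genotype, the genotype difference in each state, and the interaction (the KAT8-deficient response minus the WT response). P-values were adjusted over genes by the Benjamini-Hochberg method, the threshold was 0.05, and edgeR tests are two-sided. Standard errors are the absolute log2 fold change divided by the square root of the F statistic of the quasi-likelihood test. They refer to a change of 0 and are approximate for distances from other values. CPM values are normalised by the TMM library sizes. With groups of 2, a permutation of labels could not pass 0.05, so no p-value rests on this.

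In all, 36 gene lists (pathways, complexes and markers of cell types) were fixed, and the 32 with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01. The adjustment ran over the 32 lists within each comparison. Camera with an estimated correlation and fry were run beside it. Counts of members are given over all genes tested and adjusted over the list alone, except for the sterol list, which is given by its median and tests. R848-responsive genes were those with an adjusted p under the threshold and an absolute log2 fold change of at least 1 in the mean response over both genotypes. Intervals of medians and slopes are 95% bootstrap intervals over genes from 10000 draws. They treat genes as independent and do not measure the spread between libraries.

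Named genes follow a rule. In each pairwise comparison they are the 10 called genes with the largest rise and the 10 with the largest fall among those with at least 5 CPM in the higher group, no overlap between the libraries of the 2 groups, and no predicted or clone name. For the interaction they are the 8 largest each way without the overlap condition. Up to 4 members with the smallest adjusted p were added per list, and Kat8, Tlr7, Ifnb1, Tnf, Il6, Il12b, Il10, Cxcl10 and Isg15 were always given under R848. Other members named because a count was 5 or fewer were chosen after their values were seen. So were the predicted genes Gm20716 and Gm49388 and the responses of Lcn2 and Camp in WT cells. Some genes that meet the rule are not reported here. The main tests, the lists, the naming rule and the alternatives, except those named below, were set before the data were examined.

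The alternatives were DESeq2 size factors, no filter on low counts, a filter of at least 5 CPM in at least 2 libraries, the DESeq2 Wald test, a replicate block, the 4 libraries of each comparison alone, an added fold change threshold, responsive genes chosen in a single genotype, and leaving out each library. Robust estimation of the spread, limma-voom and an estimated correlation for the responsive genes were added after seeing the data.

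The method was tested on simulated counts drawn from the means and library sizes of the real data, with 200 of 14040 genes changed. Only genes with an expected count of at least 20 were changed, so recovery at lower counts was not tested. edgeR recovered 55.2% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 98.5% of those changed 4-fold in the WT response. The shares were 50.7%, 83.6% and 98.5% in the KAT8-deficient response, 59.7%, 83.6% and 98.5% between untreated genotypes, and 52.2%, 80.6% and 98.5% between genotypes under R848. They were 10.4%, 61.2% and 84.8% for the interaction, which had the least power. Unchanged genes called numbered 11, 11, 24, 9 and 5 in these comparisons, in the order given. Between untreated genotypes, the 24 stood beside 40, 56 and 65 recovered genes, a share of false calls above the threshold of 0.05. In the simulated genotype comparison under R848, 5 of 100 unchanged lists passed an unadjusted 0.05 with camera, 2 with an estimated correlation and 9 with fry, and all 20 lists raised 1.3-fold passed each. The simulated genes were drawn independently and the lists at random. These shares therefore do not cover real lists, whose members can vary together.

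The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9.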

Results

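Bone-marrow-derived macrophages (BMDM) are primary macrophages grown from mouse bone marrow in macrophage colony-stimulating factor (M-CSF), here at 20 ng/ml. Messenger RNA was sequenced from wild-type (WT) and KAT8-deficient BMDM, each left untreated or treated with R848 at 100 ng/ml for 6 h. KAT8, also called MOF, is a histone acetyltransferase that acts on histone H4 within the MSL and NSL complexes. R848 (resiquimod) is a small-molecule agonist of TLR7, an endosomal receptor for single-stranded RNA. The 8 libraries form 4 groups of 2. Total counts were 21384532 and 18550977 in untreated WT cells and 19033264 and 19634157 in R848-treated WT cells. They were 19016534 and 18604398 in untreated KAT8-deficient cells and 20985578 and 21217188 in R848-treated KAT8-deficient cells. Of the 34745 genes in the table, 14040 were tested, and 99.95% of all counts lay in them. The labels do not say whether the 2 libraries of a group came from separate animals or cultures, so every p-value measures only the spread between these libraries.

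Kat8 (ENSMUSG00000030801, chromosome 7, 127912516 to 127925837, GRCm38) was lower in every KAT8-deficient library than in every WT library. Untreated WT cells held 17.4 ± 0.641 CPM (normalised count relative to library size; SD, n = 2) and untreated KAT8-deficient cells 9.76 ± 1.41 (SD, n = 2). Under R848 the levels were 17 ± 1.45 in WT and 10.2 ± 0.307 in KAT8-deficient cells (SD, n = 2). The log2 difference between genotypes was -0.83 (SE 0.13, edgeR adjusted p = 0.0113) untreated and -0.74 (SE 0.12, edgeR adjusted p = 0.00553) under R848. Counts cover the whole gene and the deleted part is not given in the sources used here, so they do not say how much intact Kat8 messenger RNA remained. Of 13 genes encoding subunits of the KAT8 complexes, only Kat8 passed the edgeR test in either genotype comparison, over all genes tested or adjusted over the list alone (camera adjusted p = 0.53 untreated and 0.871 under R848 for the list). Of 12 other histone acetyltransferase genes, Kat6b was the only one to differ under R848, with a log2 difference of 0.47 (SE 0.10, edgeR adjusted p = 0.0167; 1 adjusted over the list alone, and camera adjusted p = 0.51 for the list). The untreated Kat8 difference did not pass without WT untreated replicate 1 (-0.88, adjusted p = 0.0518) or 2 (-0.79, adjusted p = 0.0589), or without KAT8-deficient untreated replicate 1 (-0.70, adjusted p = 0.0881). The R848 difference did not pass without WT R848 replicate 1 (-0.65, adjusted p = 0.0526).

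**Figure D1:**
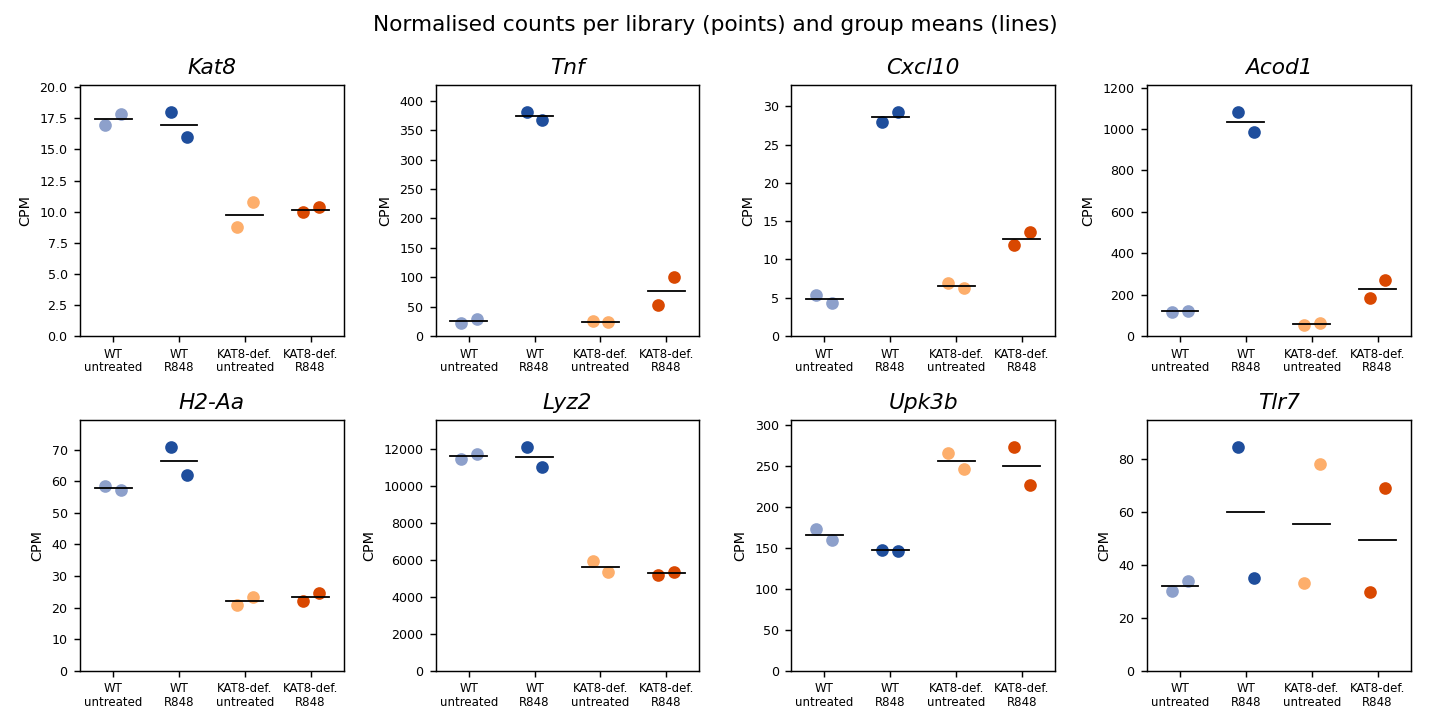
Normalised counts in CPM (y axis) of 8 genes in each library (points) of the 4 groups (x axis), with group means as lines. Kat8 ran from 8.76 to 10.8 in the 4 KAT8-deficient libraries and from 15.98 to 18.03 in the 4 WT libraries, Tnf reached 381 and 368 in WT and 51.8 and 100.9 in KAT8-deficient cells under R848, and Tlr7 replicates differed by over 2-fold in 3 of 4 groups.

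The first comparison asks which genes R848 changed in WT BMDM cultures. Genes of other cell types were also expressed there, such as the collagen gene Col1a2 at 1245 and 1394 CPM in untreated WT libraries. Which cells a change came from was not tested in this or any later comparison. Tnf, which encodes tumour necrosis factor, rose from 25.5 ± 3.78 to 375 ± 9.57 CPM (SD, n = 2), a log2 change of 3.88 (SE 0.27, edgeR adjusted p = 0.000108). Cxcl2, a neutrophil-attracting chemokine, rose from 6.87 ± 4.18 to 142 ± 6.04 CPM (SD, n = 2; log2 4.39, SE 0.46, edgeR adjusted p = 0.000479), with untreated replicates at 3.91 and 9.83 CPM. Acod1, whose product makes itaconate, rose by 3.12 (SE 0.18, edgeR adjusted p = 7.05e-05) on the log2 scale. In all, edgeR called 975 genes higher and 941 lower, 354 of them by at least 1 on the log2 scale.

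The 10 largest WT rises that met the naming rule were those of Cxcl2, Il12b (a subunit of interleukins 12 and 23), Tnf, Hcar2 (a receptor for niacin), Cxcl3, Ccl3, Rasgrp1 (a Ras exchange factor), Acod1, Clec4e (the lectin receptor Mincle) and Cxcl1. They ran from 2.98 (SE 0.24) for Cxcl1 to 4.39 for Cxcl2 on the log2 scale, with Il12b at 4.02 (SE 0.73, edgeR adjusted p = 0.00771). The 10 largest falls were those of Angptl7, Socs6, Tmem164, Lrrc14b, Rasgrp3, Daam2, Fbxo32 (a ubiquitin ligase subunit), Slc27a6 (a fatty acid transporter), Abcd2 (a peroxisomal fatty acid transporter) and Gpr183 (an oxysterol receptor). They ran from -1.51 (SE 0.20) for Gpr183 to -2.22 (SE 0.28) for Angptl7. Tmem164 had the smallest adjusted p among them, with a log2 change of -1.96 (SE 0.066, edgeR adjusted p = 8e-06). Socs6 fell by 2.05 (SE 0.53, edgeR adjusted p = 0.0354), and its untreated WT replicates stood at 68.7 and 22.7 CPM.

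Of 37 NF-kB feedback genes, 32 rose in WT cells and 0 fell over all genes tested, against 32 and 2 adjusted over the list alone. Zc3h12c rose by 2.10 (SE 0.13) and Nfkbiz by 2.01 (SE 0.14). The camera test called the list (adjusted p = 4.97e-57), with adjusted p = 0.065 with an estimated correlation. Of 17 chemokines, 12 rose and only Cxcl14 fell (12 and 1 adjusted over the list alone; camera adjusted p = 1.62e-40, and adjusted p = 0.0205 with an estimated correlation). Ccl4 rose by 2.13 (SE 0.090) and Cxcl10, an interferon-inducible chemokine, by 2.56 (SE 0.14). Among 26 inflammatory cytokine genes 17 rose and only Il10, encoding the anti-inflammatory interleukin 10, fell, by 1.62 (SE 0.23, edgeR adjusted p = 0.00252). Adjusted over the list alone, 19 rose and 2 fell (camera adjusted p = 3.86e-15, and adjusted p = 0.065 with an estimated correlation). Of 24 interferon gamma-type genes, 16 rose and 0 fell (19 and 0 adjusted over the list alone), led by the guanylate-binding protein genes Gbp2 at 1.83 (SE 0.12) and Gbp5 at 2.85 (SE 0.20). That list was called by camera (adjusted p = 3.29e-15, and adjusted p = 0.0343 with an estimated correlation). Of 48 type I interferon-stimulated genes, 21 rose and only Oas3 fell (25 and 1 adjusted over the list alone), among them Ifi205 at 2.74 (SE 0.19) and Parp14 at 1.06 (SE 0.070). The camera call on that list (adjusted p = 2.77e-16) was lost, with adjusted p = 0.315 with an estimated correlation.

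Of 27 antigen presentation and costimulation genes, 12 rose in WT cells and 0 fell (14 and 0 adjusted over the list alone; camera adjusted p = 1.79e-08). Cd40, a costimulatory receptor, rose by 2.91 (SE 0.21) and H2-Q6 by 1.38 (SE 0.10), H2-Q6 being uncertain because it shares near-identical sequence with H2-Q4 and H2-Q7. That list had adjusted p = 0.18 with an estimated correlation. Of 24 antioxidant genes controlled by NRF2, 11 rose and 0 fell (14 and 0 adjusted over the list alone; camera adjusted p = 4.83e-12), including the cystine transporter gene Slc7a11 at 2.19 (SE 0.18) and Gclm at 0.97 (SE 0.074). Its adjusted p = 0.154 with an estimated correlation. The list of 25 sterol synthesis and uptake genes had a median of 0.16 (camera adjusted p = 0.0219, and adjusted p = 0.469 with an estimated correlation). Markers of stromal and endothelial cells, other cell types that a bone marrow culture can hold, moved with R848 in WT cells. Of 13 such markers 6 fell, including Cxcl12 at -0.50 (SE 0.066), and Pdgfra alone rose, by 0.32 (SE 0.067). Adjusted over the list alone, 1 rose and 10 fell (camera adjusted p = 0.00272, and adjusted p = 0.171 with an estimated correlation).

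The WT response count fell from 1916 to 858 without WT R848 replicate 1, to 1044 without WT R848 replicate 2 and to 1139 without WT untreated replicate 2, and 18 of the 20 named genes were called whichever library was left out. Il12b did not pass without WT R848 replicate 1 or by DESeq2 (log2 3.94, adjusted p = 0.122). Socs6 was called in 3 of the 8 fits that each left out 1 library. It also did not pass with the replicate block (adjusted p = 0.0538), with robust estimation of the spread (0.179) or by limma-voom (0.0953). The sterol list lost its camera call without WT R848 replicate 2 (median 0.134). Of 33 further called genes named from the lists, 4 were lost without at least 1 library.

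The next comparison asks which genes R848 changed in KAT8-deficient BMDM cultures. Tnf rose from 24.1 ± 0.686 to 76.4 ± 34.7 CPM (SD, n = 2; log2 1.66, SE 0.26, edgeR adjusted p = 0.0398). Acod1 rose by 1.97 (SE 0.18, edgeR adjusted p = 0.00861) and Clec4e by 1.93 (SE 0.18, edgeR adjusted p = 0.00861). Mgll, which encodes monoacylglycerol lipase, rose from 22.1 ± 0.263 to 57.0 ± 0.329 CPM (SD, n = 2; log2 1.36, SE 0.074, edgeR adjusted p = 0.000464). In all, 70 genes were called higher and 19 lower, 24 of them by at least 1 on the log2 scale.

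The 10 largest rises in KAT8-deficient cells were those of H2-M2 (a non-classical MHC class I gene), Acod1, Clec4e, Fpr1 (the formyl peptide receptor), Tnf, Gbp5, Tlr2 (a lipoprotein receptor), Mgll, Adora2a (an adenosine receptor) and Nfkbie (an NF-kB inhibitor). They ran from 1.32 (SE 0.20) for Nfkbie to 2.04 (SE 0.22) for H2-M2. The 10 largest falls were those of Pheta1, Chpf2, Hsd3b7, Rab2b, Mmp2 (a gelatinase), Tfpi, Abcg1 (a cholesterol exporter), Tagln, Daglb and Ccn2. They ran from -0.51 (SE 0.083) for Ccn2 to -2.19 (SE 0.21) for Pheta1. Hsd3b7 is uncertain, since it lies within the span of the predicted gene Gm49388. In KAT8-deficient libraries Gm49388 stood at 0.2 and 0 CPM untreated and at 44.9 and 61.9 under R848. Whether reads moved between these gene models was not tested. Of the 89 genes called in KAT8-deficient cells, 78 were also called in WT cells, 77 of them in the same direction. These responses share no library, but both tests used the same estimated spread per gene from the joint fit. The overlaps of independent lists given next are therefore only a rough guide. By direction, 67 genes were higher in both, where independent lists would share 4.9, and 10 were lower in both, where independent lists would share 1.3.

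Of 17 chemokines, 6 rose in KAT8-deficient cells, including Ccl2 by 0.83 (SE 0.11) and Ccl9 by 0.78 (SE 0.069), and 13 rose adjusted over the list alone. The camera test called the list (adjusted p = 1.46e-21), with adjusted p = 0.0575 with an estimated correlation. Of 37 NF-kB feedback genes, 8 rose, including Zc3h12c by 1.14 (SE 0.13) and Sod2 by 1.01 (SE 0.13), and 24 rose and 2 fell adjusted over the list alone. The list was called (camera adjusted p = 2.01e-26), with adjusted p = 0.22 with an estimated correlation. Acod1, Il1a and Tnf were the 3 of 26 inflammatory cytokine genes that rose (5 adjusted over the list alone; camera adjusted p = 7.3e-06, and adjusted p = 0.22 with an estimated correlation). Gbp2 and Gbp5 were the 2 of 24 interferon gamma-type genes that rose (3 adjusted over the list alone; camera adjusted p = 5.56e-07, and adjusted p = 0.136 with an estimated correlation). Parp14 and Cxcl10 were the 2 of 48 type I interferon-stimulated genes that rose, against 12 higher and 1 lower adjusted over the list alone (camera adjusted p = 3.88e-08, and adjusted p = 0.434 with an estimated correlation). H2-Q6 and H2-Q4, both uncertain as near-identical copies, rose among 27 antigen presentation genes (2 adjusted over the list alone). The list had camera adjusted p = 0.000947, and adjusted p = 0.381 with an estimated correlation. Of 13 stromal and endothelial markers, Tagln and Acta2 fell (4 adjusted over the list alone; camera adjusted p = 0.00063, and adjusted p = 0.22 with an estimated correlation).

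Camera called 10 further lists in KAT8-deficient cells, each with at most 1 member past the edgeR test. The medians of the lists of mitochondrially encoded genes (0.24), sterol synthesis (0.17), NRF2 antioxidant genes (0.07) and endosomal TLR signalling (0.05) were above 0. Those of replication-dependent histones (-0.52), immediate early genes (-0.14), glycolysis (-0.12), cell cycle (-0.085), ribosomal proteins (-0.081) and nuclear-encoded oxidative phosphorylation genes (-0.048) were below 0. The calls were lost in each, with adjusted p = 0.22 at the lowest and adjusted p = 0.696 at the highest with an estimated correlation. Gclm, of the NRF2 list, rose by 0.53 (SE 0.076), and Ikbke, of the endosomal TLR list, by 0.68 (SE 0.086). Adjusted over the list alone, 9 NRF2 genes, 6 mitochondrially encoded genes, 2 endosomal TLR genes and 1 ribosomal protein gene were higher and 1 histone gene lower. By the same adjustment, 1 glycolysis gene was higher and 2 lower, and 0 genes passed in the immediate early, cell cycle and oxidative phosphorylation lists.

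The KAT8-deficient response rested on single libraries more than the other comparisons. From 89, the count became 2 without KAT8-deficient untreated replicate 1, 31 without KAT8-deficient untreated replicate 2, 40 without KAT8-deficient R848 replicate 2, 186 without KAT8-deficient R848 replicate 1, and 17 and 20 without WT R848 replicates 1 and 2. Only Mgll of the 20 named genes was called whichever library was left out, and without KAT8-deficient R848 replicate 1 the interferon-stimulated list lost its call (camera adjusted p = 0.138), as did 8 of the 10 further lists without at least 1 library, for example the ribosomal protein list without KAT8-deficient untreated replicate 1 (camera adjusted p = 0.836). Of the 20 named genes, 16 did not pass with only the 4 libraries compared, and 10 of the 20 did not pass under another processing alternative, for example Tnf with robust estimation of the spread (adjusted p = 0.172) or limma-voom (0.0622). Acod1, Clec4e, Mgll and Pheta1 passed under each of these. Of 16 further called genes named from the lists, 13 were lost under at least 1 of these alternatives and each was lost without at least 1 library.

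The untreated genotype comparison asks what KAT8 deficiency changed before stimulation. H2-Aa, Cd74 and H2-Eb1, which serve MHC class II antigen presentation, were lower. H2-Aa, a class II chain, stood at 57.8 ± 0.957 CPM in WT and 22.03 ± 1.68 in KAT8-deficient cells (SD, n = 2; log2 -1.39, SE 0.097, edgeR adjusted p = 0.000417), and Cd74, the invariant chain, at -1.38 (SE 0.10, edgeR adjusted p = 0.000466). Gdpd3, a lysophospholipase D gene on chromosome 7 (126766334 to 126775649, GRCm38), was the most raised named gene, at 46.3 ± 3.98 against 2.62 ± 0.141 CPM (SD, n = 2; log2 4.14, SE 0.16, edgeR adjusted p = 1.07e-05). In all, 409 genes were called higher and 191 lower in KAT8-deficient cells, 103 of them by at least 1 on the log2 scale.

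The 10 largest rises without R848 were those of Gdpd3, Pheta1, Lyz1, Wdfy1, Dynlt1b, Arg1 (arginase), Mab21l2, Tshz2, Ptn (pleiotrophin) and Fmo2 (a flavin-containing monooxygenase). They ran down to 1.43 (SE 0.28) for Fmo2, with Arg1 at 1.60 (SE 0.16, edgeR adjusted p = 0.00268) and Lyz1, a lysozyme gene nearly identical to Lyz2 and so uncertain, at 1.99 (SE 0.10, edgeR adjusted p = 6.13e-05). Dynlt1b is uncertain for the same reason, having near-identical copies. The 10 largest falls were those of Ccl8 and Ccl5 (chemokines), Cdkn1c (a cyclin-dependent kinase inhibitor), Mgll, Mrgpre, Cfb (complement factor B), H2-Aa, Cd74, Slc6a12 (a betaine transporter) and H2-Eb1. They ran from -1.29 (SE 0.12) for H2-Eb1 to -2.57 (SE 0.25) for Ccl8. Cdkn1c differed by -2.36 (SE 0.078, edgeR adjusted p = 7.05e-06) and Mgll by -2.07 (SE 0.074, edgeR adjusted p = 7.05e-06). Cfb differed by -1.46 (SE 0.30, edgeR adjusted p = 0.0359), and its R848-treated KAT8-deficient replicates stood at 20.0 and 45.5 CPM. Cfb is uncertain, since its exons overlap those of another gene on the same strand.

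Of 27 antigen presentation and costimulation genes, 14 were lower and 0 higher in untreated KAT8-deficient cells (19 lower and 1 higher adjusted over the list alone), with a median log2 difference of -0.39. The camera test called the list (adjusted p = 5.28e-28), with adjusted p = 0.0724 with an estimated correlation. Gbp2, Gbp3, Tap2 and Psmb8 were the 4 of 24 interferon gamma-type genes that were lower (10 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00172, and adjusted p = 0.273 with an estimated correlation). Irf7, Oas3, Phf11d and Oasl2 were the 4 of 48 type I interferon-stimulated genes that were lower (5 adjusted over the list alone; camera adjusted p = 0.000921, and adjusted p = 0.801 with an estimated correlation). Irf7, a transcription factor of interferon induction, differed by -0.76 (SE 0.15). Acod1 and Ebi3 were lower and Il1rn higher among 26 inflammatory cytokine genes (3 higher and 5 lower adjusted over the list alone), with camera adjusted p = 0.398 for the list.

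Of 13 stromal and endothelial markers, 9 were higher and 0 lower in untreated KAT8-deficient cells (10 higher and 1 lower adjusted over the list alone), with a median of 0.44. Lum, a collagen-binding proteoglycan gene, differed by 1.05 (SE 0.14), Col3a1 by 0.88 (SE 0.12) and Acta2, encoding smooth muscle actin, by 0.58 (SE 0.073). The list was called (camera adjusted p = 1.24e-11), with adjusted p = 0.0724 with an estimated correlation. These markers thus moved with genotype beside each gene group above. The list of 25 sterol synthesis and uptake genes had a median of 0.19 (camera adjusted p = 3.58e-05, and adjusted p = 0.3 with an estimated correlation). Ube2c was the only 1 of 50 cell cycle genes that was higher (1 adjusted over the list alone; camera adjusted p = 0.000843, and adjusted p = 0.184 with an estimated correlation). Tpi1 was the only 1 of 24 glycolysis genes that was higher (7 adjusted over the list alone; camera adjusted p = 0.0173, and adjusted p = 0.408 with an estimated correlation). Of 42 macrophage identity genes, C5ar1 and Maf were higher and Lyz2, Ctss and Mpeg1 lower (6 higher and 4 lower adjusted over the list alone), with camera adjusted p = 0.886 for the list. Lyz2, encoding lysozyme, was lower by a log2 difference of -1.04 (SE 0.069, edgeR adjusted p = 0.000304). It stood at 11470 and 11750 CPM in untreated WT and at 5944 and 5340 in untreated KAT8-deficient libraries. Its copy Lyz1 held 81.2 and 73.8 CPM in the latter, which argues against reads moved to Lyz1 as the cause of this fall.

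Without single libraries the untreated count of 600 fell to 66 (KAT8-deficient untreated replicate 1), 172 (KAT8-deficient untreated replicate 2), 165 and 228 (WT untreated replicates 1 and 2), and 341 and 391 (WT R848 replicates 1 and 2), and 14 of the 20 named genes were called throughout. Over the 8 fits that each left out 1 library, Cfb was called in 2 and Fmo2 in 4. Mab21l2 and Ptn were called in 5 of them, Slc6a12 in 6 and Ccl5 in 7. The interferon-stimulated list lost its camera call without WT untreated replicate 1. The glycolysis list lost its call without that library or without KAT8-deficient untreated replicate 1. Cfb was also lost with robust estimation of the spread (adjusted p = 0.158). Of 28 further called genes named from the lists, 22 were lost without at least 1 library. Other alternatives ended the calls of Gbp2 and Gbp3 (limma-voom, adjusted p = 0.0707 and 0.0535), Tap2, Psmb8 and Ube2c (the 4 libraries compared alone, 0.0858, 0.068 and 0.06), Psmb8 also by DESeq2 (0.0604), and Oasl2 (replicate block, 0.0597).

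The main genotype comparison asks what KAT8 deficiency changed under R848. Tnf, Il12b, Cxcl10 and Isg15, which serve inflammation and the interferon response, were lower in KAT8-deficient cells. Tnf stood at 76.4 ± 34.7 against 375 ± 9.57 CPM in WT (SD, n = 2; log2 -2.30, SE 0.25, edgeR adjusted p = 0.00089), and Il12b at 0.613 ± 0.4 against 9.61 ± 2.47 (SD, n = 2; log2 -3.96, SE 0.71, edgeR adjusted p = 0.00778). Cxcl10 differed by -1.17 (SE 0.13, edgeR adjusted p = 0.000857) and Isg15, a ubiquitin-like interferon-stimulated gene, by -0.97 (SE 0.15, edgeR adjusted p = 0.00358). Il10 was higher, by a log2 difference of 1.58 (SE 0.23, edgeR adjusted p = 0.00312), at 3.02 and 3.58 CPM against 0.919 and 1.28 in WT. In all, 1143 genes were called higher and 768 lower, 405 of them by at least 1 on the log2 scale.

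Il6 stood near 1 CPM in every group and did not pass the test under R848 (log2 -0.29, SE 0.41, edgeR adjusted p = 0.692), and its sign changed to 0.20 without KAT8-deficient R848 replicate 1. Tlr7, the R848 receptor, did not pass either (log2 -0.28, SE 0.51, edgeR adjusted p = 0.769). Its replicates stood at 84.7 and 35.2 CPM in WT and at 29.6 and 69.1 in KAT8-deficient cells, and the sign changed without WT R848 replicate 1 (0.49) or KAT8-deficient R848 replicate 1 (0.21). Ifnb1, encoding interferon beta, had 1 count over all 8 libraries and was not detectable at this depth, where 3 counts correspond to 0.14 to 0.162 CPM. The 15 interferon genes as a list held at most 3 counts in a library and were not tested.

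The 10 largest falls under R848 were those of Il12b, Cxcl2, Il1b (interleukin 1 beta), Rasgrp1, Chpf2, Cxcl3, Vnn3 (a vanin pantetheinase), Ccl3, Slc7a2 (an arginine transporter) and Tnf. Cxcl2 differed by -3.04 (SE 0.42, edgeR adjusted p = 0.00215), with KAT8-deficient replicates at 9.47 and 24.9 CPM, and Rasgrp1 by -2.81 (SE 0.18, edgeR adjusted p = 0.000145). The 10 largest rises were those of Gdpd3, Pcdhgb5, Fmo2, Megf6, Fam84a, Angptl7, Lyz1, Daam2, Plekha6 and Pcp4l1. They ran from 1.77 (SE 0.20) for Pcp4l1 to 4.26 (SE 0.17) for Gdpd3. Pcdhgb5 (2.55, SE 0.66, edgeR adjusted p = 0.036) is uncertain, since the gene models of its protocadherin cluster overlap.

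Of 17 chemokines, 12 were lower under R848 and only Cxcl5 and Cxcl14 higher (12 and 2 adjusted over the list alone). Ccl5 differed by -1.72 (SE 0.15) and Ccl4 by -1.46 (SE 0.087), and the list was called (camera adjusted p = 2.97e-16, and adjusted p = 0.0288 with an estimated correlation). Of 27 antigen presentation genes, 22 were lower and 0 higher (25 and 0 adjusted over the list alone), H2-Aa at -1.51 (SE 0.096) among them (camera adjusted p = 9.58e-35, and adjusted p = 0.0288 with an estimated correlation). Of 24 interferon gamma-type genes, 11 were lower and 0 higher (14 and 0 adjusted over the list alone), with Gbp5 at -2.13 (SE 0.19) and Gbp2 at -1.55 (SE 0.11). That list was called (camera adjusted p = 1.15e-14, and adjusted p = 0.0288 with an estimated correlation). Of 37 NF-kB feedback genes, 27 were lower and 0 higher (30 and 0 adjusted over the list alone), with Malt1 at -1.58 (SE 0.13) and the adhesion molecule gene Icam1 at -1.53 (SE 0.15). Its call (camera adjusted p = 1.86e-26) had adjusted p = 0.123 with an estimated correlation. Of 26 inflammatory cytokine genes, 14 were lower and only Il10 higher (17 and 2 adjusted over the list alone), with Acod1 at -2.19 (SE 0.17) and Il1a at -0.96 (SE 0.10). Its call (camera adjusted p = 1.42e-10) had adjusted p = 0.07 with an estimated correlation. Of 48 type I interferon-stimulated genes, 23 were lower and 0 higher (24 and 0 adjusted over the list alone), with Ifi205 at -1.60 (SE 0.17) and Parp14 at -0.64 (SE 0.069). Its call (camera adjusted p = 2.84e-15) had adjusted p = 0.27 with an estimated correlation.

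Of 13 stromal and endothelial markers, 11 were higher and 0 lower under R848 (12 higher and 1 lower adjusted over the list alone), with a median of 0.44, beside each gene group of this comparison. Lum differed by 1.496 (SE 0.148) and Col3a1 by 1.17 (SE 0.12), and the list was called (camera adjusted p = 1.42e-10, and adjusted p = 0.0288 with an estimated correlation). Of 42 macrophage identity genes, 7 were higher and 10 lower (13 and 13 adjusted over the list alone), with a median of 0.02 although the camera test pointed down (adjusted p = 0.91). Lyz2, the macrophage marker with the smallest adjusted p, differed by -1.14 (SE 0.069, edgeR adjusted p = 0.000143). Of 24 NRF2 antioxidant genes, 10 were lower and 0 higher (12 lower and 1 higher adjusted over the list alone), with Slc7a11 at -1.86 (SE 0.18) and Abcc1 at -0.70 (SE 0.087). Its call (camera adjusted p = 5.21e-07) had adjusted p = 0.201 with an estimated correlation. Of 20 LXR target and fatty acid genes, 8 were higher and only Nr1h2 lower (10 and 3 adjusted over the list alone), with the cholesterol exporter gene Abcg1 at 0.59 (SE 0.093) and Plin2, a lipid droplet gene, at 0.42 (SE 0.065). Its call (camera adjusted p = 0.00261) had adjusted p = 0.328 with an estimated correlation. The list of 25 sterol synthesis and uptake genes had a median of 0.18 (camera adjusted p = 0.00639, and adjusted p = 0.391 with an estimated correlation). Rrm1, Pcna, Cenpf and Kif11 were the 4 of 50 cell cycle genes that were higher (1 adjusted over the list alone; camera adjusted p = 0.00848, and adjusted p = 0.163 with an estimated correlation). Of 7 neutrophil markers, Lcn2, Mmp9 and Camp were lower (5 adjusted over the list alone; camera adjusted p = 0.00177, and adjusted p = 0.123 with an estimated correlation). Lcn2 encodes an iron-sequestering protein and Camp an antimicrobial peptide, and both rose with R848 in WT cells, by 1.39 (SE 0.21) and 4.61 (SE 0.87).

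**Figure D2:**
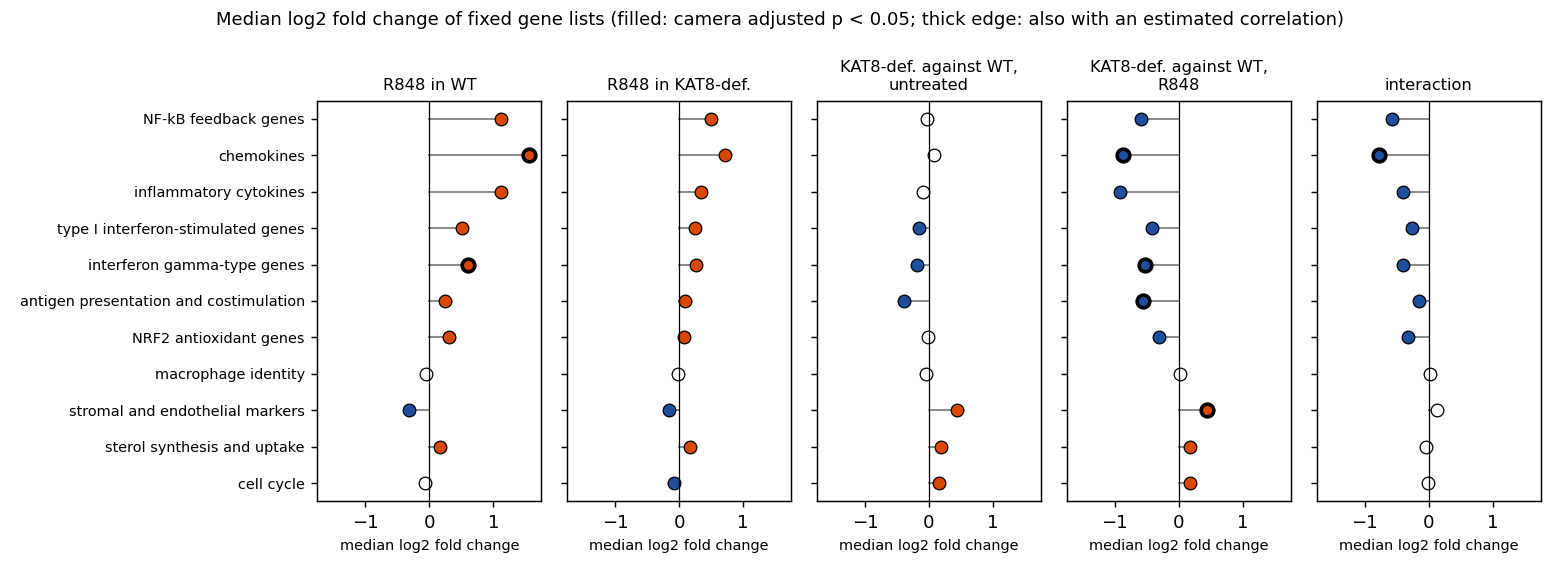
Median log2 fold change (x axis) of 11 fixed gene lists (y axis) in the 5 comparisons, with points filled where camera called the list and thick edges where the call held with an estimated correlation. Chemokines had medians of 1.55 in the WT response, 0.71 in the KAT8-deficient response and -0.88 between genotypes under R848, and stromal markers stood at 0.44 in both genotype comparisons.

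The count of 1911 under R848 fell to 784 without WT R848 replicate 1, to 1025 without WT R848 replicate 2 and to 976 without KAT8-deficient R848 replicate 1, and 17 of the 20 named genes were called whichever library was left out. Of the 8 fits that each left out 1 library, Pcdhgb5 was called in 1, and Il12b and Il1b in 6 each. Il12b also missed the threshold by DESeq2 (adjusted p = 0.121). Pcdhgb5 missed it with robust estimation (adjusted p = 0.118), limma-voom (0.155) or the 4 libraries compared alone (0.0966). The sterol list lost its camera call without KAT8-deficient R848 replicate 1 (median 0.145). Of 58 further called genes named from the lists or always given, 12 were lost without at least 1 library. Other alternatives ended the calls of Pcna, Cenpf and Kif11 (DESeq2, adjusted p = 0.0777, 0.0883 and 0.0942), Mmp9 (robust estimation, 0.0954) and Camp (no filter on low counts, 0.068). Cenpf and Kif11 were also lost with the replicate block (0.059 and 0.0551) and, like Mmp9, with the 4 libraries compared alone (0.071, 0.0769 and 0.0674), and Kif11 with DESeq2 size factors (0.0523) and limma-voom (0.0503).

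Of the 600 genes called between genotypes without R848, 430 were also called under R848, 425 of them in the same direction, and these comparisons share no library. By direction, 315 genes were higher in both, where independent lists would share 33.3, and 110 were lower in both, where independent lists would share 10.4. The labels do not say whether untreated and R848 libraries of a genotype came from the same animals or cultures. The 2 comparisons may therefore not be independent, and their tests also used the same estimated spread per gene from the joint fit. The log2 differences of the 2 comparisons correlated with r = 0.416 across genes, which are not independent replicates. Gdpd3 lies near Kat8 on chromosome 7. Within 2 Mb of Kat8, 6 other genes were called in both comparisons in the same direction: Lat, Coro1a, Mapk3 and Gdpd3 were higher, and Spn and Itgal lower. These 6 were chosen after their values were seen. Mapk3, encoding the kinase ERK, differed by 0.90 untreated and 1.05 under R848, and Itgal, an integrin chain, by -1.12 and -1.55.

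**Figure D3:**
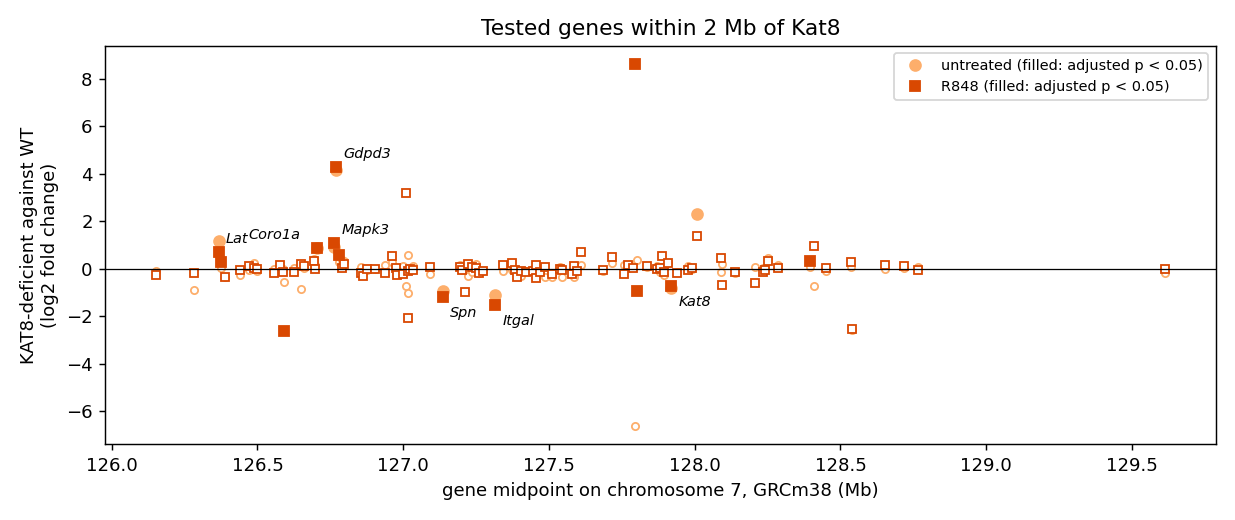
Log2 difference between KAT8-deficient and WT cells (y axis) of tested genes within 2 Mb of Kat8 by midpoint on chromosome 7 in Mb (x axis), untreated (circles) and under R848 (squares), filled where the edgeR adjusted p passed. Gdpd3 stood at 4.14 and 4.26 and Kat8 at -0.83 and -0.74, and labels mark the genes called in both comparisons.

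The interaction asks whether the response to R848 differed between genotypes. Ccl3, Ccl4 and Cxcl10, which encode chemokines, responded less in KAT8-deficient cells. Ccl3 rose by 3.30 on the log2 scale in WT, and its change of 0.97 in KAT8-deficient cells did not pass (edgeR adjusted p = 0.0993). The difference between these responses was -2.33 (SE 0.29, edgeR adjusted p = 0.0278). Ccl4 (-1.57, SE 0.13, edgeR adjusted p = 0.00342) and Cxcl10 (-1.60, SE 0.20, edgeR adjusted p = 0.0252) also differed. Tmem164 fell by 1.96 in WT, from 218 ± 9.44 to 55.8 ± 1.56 CPM, and stood at 189 ± 8.73 and 180 ± 3.15 in KAT8-deficient cells (SD, n = 2; interaction 1.89, SE 0.091, edgeR adjusted p = 0.000163). In all, 24 genes had a lower and 8 a higher log2 response in KAT8-deficient cells.

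The 8 largest negative interactions were those of Pheta1, Ccl3, Hcar2, Cd40, Ifi205, Cxcl10, Ccl4 and Nfkbiz, from -1.48 (SE 0.19) for Nfkbiz to -4.38 (SE 0.29) for Pheta1. Pheta1, an endosomal trafficking gene, rose by 2.19 with R848 in WT and fell by 2.19 in KAT8-deficient cells. It stood at 1.54 and 2.55 CPM in untreated and 9.12 and 9.39 in R848-treated WT libraries. In KAT8-deficient libraries it stood at 10.02 and 9.42 untreated and 1.98 and 2.26 under R848. Whether reads divided between gene models shaped these levels was not tested. Among the 7 positive interactions that met the naming rule were those of Tmem164, Mgll, Fbxo32, Xylt1, Daglb and Dhrs3. Mgll had a WT response of 0.06 (SE 0.069, edgeR adjusted p = 0.638) and an interaction of 1.31 (SE 0.10, edgeR adjusted p = 0.00291). The predicted gene Gm20716 was also called higher.

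Of 17 chemokines, 6 had a weaker response by the interaction test (9 adjusted over the list alone; camera adjusted p = 1.14e-23, and adjusted p = 0.0389 with an estimated correlation). Marcksl1, Nfkbiz and Socs3, a suppressor of cytokine signalling, were the 3 of 37 NF-kB feedback genes called lower (26 adjusted over the list alone; camera adjusted p = 5.42e-34, and adjusted p = 0.175 with an estimated correlation). Inhba, an activin subunit gene, was the only 1 of 26 cytokine genes called (7 lower and 1 higher adjusted over the list alone; camera adjusted p = 7.37e-08, and adjusted p = 0.175 with an estimated correlation). Tnf had an interaction of -2.22 (SE 0.36, edgeR adjusted p = 0.0575). Cxcl10 and Ifi205 were the 2 of 48 type I interferon-stimulated genes called lower (5 adjusted over the list alone; camera adjusted p = 6.19e-09, and adjusted p = 0.567 with an estimated correlation). Cd40 was the only 1 of 27 antigen presentation genes called lower (4 adjusted over the list alone; camera adjusted p = 2.25e-05, and adjusted p = 0.432 with an estimated correlation). The interferon gamma-type list, with Gbp2 at -0.98 (SE 0.16, edgeR adjusted p = 0.0583), had 0 of 24 genes called by edgeR over all genes tested and 4 lower adjusted over the list alone (camera adjusted p = 9.93e-09, and adjusted p = 0.097 with an estimated correlation). The NRF2 list, with Slc7a11 at -1.38 (SE 0.25, edgeR adjusted p = 0.0684), had 0 of 24 genes called by edgeR over all genes tested and 11 lower adjusted over the list alone (camera adjusted p = 2.28e-09, and adjusted p = 0.212 with an estimated correlation).

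The interaction count of 32 became 6 without KAT8-deficient untreated replicate 1, 11 without KAT8-deficient untreated replicate 2, 11 without either WT R848 replicate 1 or WT R848 replicate 2, 19 without WT untreated replicate 2, and 208 without KAT8-deficient R848 replicate 2. The balance of 24 lower and 8 higher changed as well: it was 4 and 7 without WT R848 replicate 1, 5 and 6 without WT R848 replicate 2 or KAT8-deficient untreated replicate 2, 3 and 3 without KAT8-deficient untreated replicate 1, 13 and 12 without WT untreated replicate 1, 12 and 7 without WT untreated replicate 2, and 31 and 9, and 141 and 67, without KAT8-deficient R848 replicates 1 and 2. Of the 15 named genes, Tmem164, Mgll, Fbxo32, Pheta1 and Ccl4 were the 5 called whichever library was left out. Under at least 1 other alternative Ccl3 (robust estimation, adjusted p = 0.0866), Hcar2 and Cd40 (limma-voom, 0.0643 and 0.0588), and Ifi205, Daglb and Socs3 (replicate block, 0.0668, 0.0559 and 0.0646) did not pass. Ifi205 was also lost with limma-voom (0.076), and Hcar2 and Ifi205 with the filter of at least 5 CPM (0.0504 and 0.0555). The 4 further called genes named from the lists were each lost without at least 1 library.

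R848-responsive genes were also taken from the mean response over both genotypes, a choice that does not favour either genotype in this balanced design. Of the 125 raised genes, 114 (91.2%) were lower in KAT8-deficient cells under R848, 86 of them by edgeR over all genes, and 113 (90.4%) had a weaker response. Their median response was 1.86 in WT and 0.98 in KAT8-deficient cells, and their median genotype difference was -1.17 under R848 (camera p = 1.48e-75, and p = 0.00591 with an estimated correlation) against -0.19 without it. Of the 36 lowered genes, 30 (83.3%) had a weaker response and 19 were called higher in KAT8-deficient cells under R848. The lowered genes had a median response of -1.58 in WT and -0.78 in KAT8-deficient cells, and a median genotype difference of 1.18 under R848 (camera p = 6.26e-13, and p = 0.00932 with an estimated correlation). The median of the lowered genes was 0.18 without KAT8-deficient R848 replicate 2 and 0.69 without KAT8-deficient R848 replicate 1, while that of the raised genes ran from -1.33 to -0.92 whichever library was left out.

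**Figure D4:**
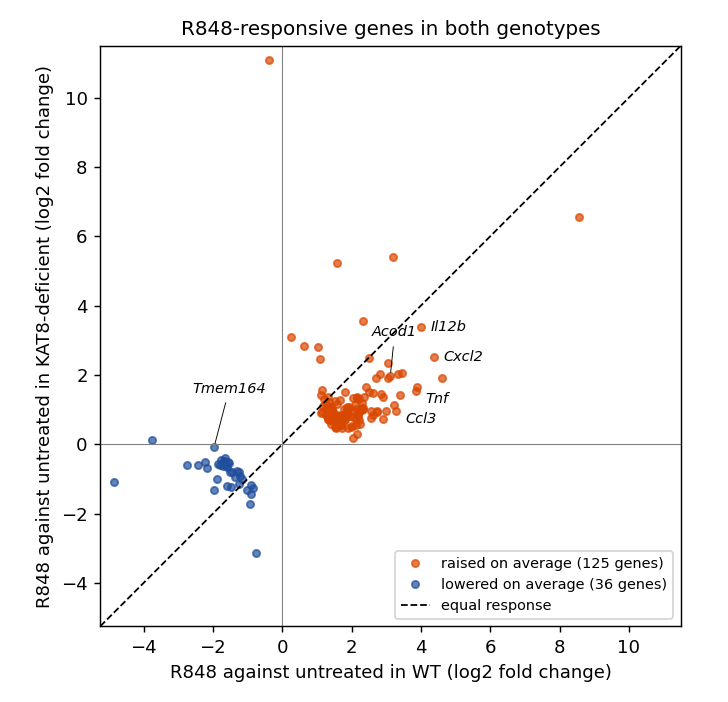
Log2 response to R848 in KAT8-deficient cells (y axis) against that in WT cells (x axis) for 125 raised and 36 lowered genes (points), with the dashed line at equal responses. Of the raised genes 113 lie below the line, Tnf at 3.88 in WT and 1.66 in KAT8-deficient cells.

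Across the 5 comparisons camera called 52 of the list tests, and 7 held with an estimated correlation. These were the chemokine and interferon gamma-type lists in the WT response, the chemokine, interferon gamma-type, antigen presentation and stromal lists between genotypes under R848, and the chemokine list in the interaction. Camera called 13 lists in no comparison. They were the 2 lists of acetyltransferase genes, macrophage identity, alternative activation, mitochondrial gene expression machinery, p53 targets, DNA repair, lysosome and autophagy, the integrated stress and unfolded protein responses, heat shock genes, and markers of monocytes and progenitors, dendritic cells and lymphocytes. The lowest camera adjusted p among them was 0.0783, for the stress response list between untreated genotypes. Arg1, of the alternative activation list, was higher in KAT8-deficient cells under R848 as well, by 1.69 (SE 0.17, edgeR adjusted p = 0.000684). Mast cell markers (15 to 53 counts in all per library), erythroid and megakaryocyte markers (614 to 781) and the sex-linked genes had fewer than 5 tested members and were not tested as lists.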

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

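The test of the macrophage share and that of the difference between slopes were chosen only after the result was seen, and the others were set before it.

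The response to R848 differed between genotypes by the interaction test itself for 32 genes. The KAT8-deficient response minus the WT response was 1.89 for Tmem164, 1.31 for Mgll, 1.302 for Fbxo32, 0.77 for Xylt1, 0.70 for Daglb and 0.63 for Dhrs3 on the log2 scale. It was -4.38 for Pheta1, -2.33 for Ccl3, -2.31 for Hcar2, -2.18 for Cd40, -1.82 for Ifi205, -1.60 for Cxcl10, -1.57 for Ccl4 and -1.48 for Nfkbiz. Of the fixed lists, chemokines had a median difference of -0.77, NF-kB feedback genes of -0.56, interferon gamma-type genes of -0.41, inflammatory cytokines of -0.40, NRF2 antioxidant genes of -0.32, type I interferon-stimulated genes of -0.26 and antigen presentation genes of -0.14. Of these lists, only chemokines were called with an estimated correlation.

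The weaker response of KAT8-deficient cells to R848 was weighed against technical explanations. A single weakly stimulated library is argued against as the whole cause. The median genotype difference of the raised genes was -0.917 without KAT8-deficient R848 replicate 1 and -1.33 without replicate 2. Induction was still uneven between these libraries. Replicates 1 and 2 held 51.8 and 100.9 CPM of Tnf, 181 and 271 of Acod1, and 210 and 326 of Clec4e. Cxcl10 was closer, at 11.8 and 13.6, and Isg15 went the other way, at 9.33 and 7.5. A lower share of macrophages as the whole cause is argued against. The median of 42 macrophage identity genes under R848 had a bootstrap interval over genes of -0.091 to 0.174. This lay above the median of -1.17 of the raised genes. Weaker exposure of the KAT8-deficient cultures to R848 was expected to give raised and lowered genes the same slope of the KAT8-deficient on the WT response, and the slopes were 0.578 (0.506 to 0.648) and 0.371 (0.269 to 0.522), each outside the other's interval, with a difference of 0.207 (0.036 to 0.331). Weaker exposure still cannot be told apart from an effect of genotype, since the interval of this difference reached below 0 without WT untreated replicate 2 (-0.048 to 0.278) or KAT8-deficient R848 replicate 2 (-0.12 to 0.244). With 1 dose it is also not known whether all genes would keep the same fraction. Nor is it known whether the raised and the lowered genes responded in the same cells, without which equal slopes need not follow. An effect of KAT8 on inflammatory gene induction, the difference the design names, may underlie the pattern and stays among the open explanations as untested.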

How the results depend on the processing

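Robust estimation of the spread, limma-voom and the estimated correlation for the responsive genes were alternatives chosen after seeing the data. DESeq2 size factors, the filter of at least 5 CPM in at least 2 libraries and limma-voom kept all 10 main results within 1.5 times their count or on their side of the threshold. DESeq2 size factors gave 1920, 95, 590, 1909 and 33 genes for the WT response, the KAT8-deficient response, the untreated and R848 genotype comparisons and the interaction. The count of the KAT8-deficient response (89) became 274 with no filter, 235 with the DESeq2 Wald test, 158 with robust estimation and 22 with only the 4 libraries compared, and that of the interaction (32) became 245, 227 and 148 under the first 3 of these. The untreated genotype count of 600 became 384 with only the 4 libraries compared. For these changes the cause was not tested. With an added absolute log2 fold change of at least 1 the counts were by construction lower, at 354 for the WT response, 24 for the KAT8-deficient response, 103 untreated and 405 under R848. Of 52 list calls 7 held with an estimated correlation and 32 with fry. Taking responsive genes from KAT8-deficient cells alone reversed the median of the lowered genes to -1.53, over 4 genes that share the KAT8-deficient R848 libraries by construction. Leaving out each library in turn, which leaves a lone library assumed to vary like the other groups, gave 858 to 1826 genes for the WT response, 2 to 186 for the KAT8-deficient response, 66 to 606 untreated, 784 to 1894 under R848 and 6 to 208 for the interaction. It gave Kat8 differences of -0.99 to -0.70 untreated and -0.82 to -0.65 under R848, 46 to 56 list calls, and medians of -1.33 to -0.92 for raised and 0.18 to 1.29 for lowered genes. Signs reversed for Il6 (-1.03 to 0.20, highest without KAT8-deficient R848 replicate 1) and Tlr7 (-1.01 to 0.49, with 0.49 without WT R848 replicate 1 and 0.21 without KAT8-deficient R848 replicate 1), neither of which passed the test, and for the ribosomal protein list in the KAT8-deficient response (medians of -0.113 to -0.007, the latter without KAT8-deficient untreated replicate 1, where camera pointed up). For these too the cause was not tested. Deviations between replicates correlated at -0.027 to 0.05 over 6 pairs of groups. The labels do not say whether replicates with the same number shared an animal or culture, and these correlations cannot exclude it. A replicate block gave 1875, 73, 531, 1871 and 25 genes in the order above, and 50 list calls. Of 310 values of named genes, 309 kept their direction and side of the threshold with DESeq2 size factors, 293 with the block, and 225 to 273 when a library was left out. Alternatives planned for normalised values (another pseudocount, quantile normalisation) did not apply to counts and were not run. Depth limits genes below about 0.14 to 0.162 CPM.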

Other observations

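The tests on stromal cells, on DNA near Kat8 and on Lyz2 were chosen only after the result was seen, and those on replicates were planned before it.

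Genes typical of mesothelium, the lining of body cavities, were detected in these cultures, at mean levels from 4.05 CPM for Rspo1 to 173 CPM for Lrrn4 in untreated WT cells. A list of 15 such genes was written after the values were seen, and 14 were tested, so the list describes these values and tests no explanation. None of them is in another list, and the labels name no sort or gate that would remove such cells. Upk3b, a uroplakin gene, stood at 172 and 160 CPM in untreated WT and at 266 and 246 in untreated KAT8-deficient libraries (log2 0.62, SE 0.092, edgeR adjusted p = 0.0111). Lrrn4 differed by 0.46 (SE 0.077) untreated and 0.74 (SE 0.078) under R848, and Gpm6a by 0.85 (SE 0.14) and 1.27 (SE 0.15). Over the list, 8 genes were higher untreated (13 adjusted over the list alone, median 0.58), and 14 under R848 (14 adjusted over the list alone, median 0.96). In the WT response 6 were lower (7 adjusted over the list alone, median -0.35), and in the KAT8-deficient response edgeR called 0 (0 adjusted over the list alone, median -0.055). The interaction had a median of 0.41, with 0 genes called by edgeR and 2 higher adjusted over the list alone. Col1a2, the abundant collagen gene, stood at 1245 and 1394 CPM in untreated WT and 1672 and 1614 in untreated KAT8-deficient libraries.

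The genotype differences shared by both genotype comparisons were weighed against 3 explanations. The median untreated difference of the stromal list had a bootstrap interval over genes of 0.2 to 0.578. The 11 markers of this list with a mean of at least 20 CPM ran from 0.093 to 1.05, a range that 1 shift common to all of them does not describe. A larger share of stromal cells in the KAT8-deficient cultures may account for part of the shared differences. For the most raised genes it cannot be told apart from other explanations: 18 of the 315 genes higher in both comparisons, led by Cmah, Gdpd3, Slc15a2 and Prph, lay over 2 SE above the most raised abundant stromal marker at 1.05, and a change within such cells stays open. DNA carried along with the targeted allele stays open for genes near Kat8: 11.5% of 11775 windows of as many tested genes elsewhere held as many genes called in both comparisons as the 6 near Kat8, so chance cannot be told apart from linkage. A Cre driver placed in Lyz2, which the labels do not name, could underlie the lower Lyz2, which lay at most 1.98 SE from -1, the loss of 1 of 2 copies, while an effect of KAT8 on these genes stays open and untested.

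Replicates of the same group differed by over 2-fold at 120 of 9187 abundant genes (1.31%), Tlr7, Cxcl2, Socs6 and Cfb among them. Xiap, an inhibitor of apoptosis, stood at 90.6 and 29.8 CPM in R848-treated WT and at 81.1 and 23.8 in untreated KAT8-deficient libraries. Sampling noise is argued against, since 20 tables drawn with the fitted trend of spread over abundance held at most 3 such genes. These draws left out any larger spread of single genes, which therefore stays open. Reads divided between overlapping or alternative gene models may account for part: 29 of 119 discordant genes with an annotation overlap another gene on their strand, against a median of 11 in 10000 draws matched on abundance (permutation p = 1e-04, the smallest they can give). Among the genes named above, Cfb overlaps another gene on its strand, while Tlr7, Cxcl2, Socs6 and Xiap do not. No biological explanation was tested, and discordant genes without such an overlap stay unexplained.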
